A study of Mus musculus with 6 samples.

How the data were processed

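Total RNA from CD4+ T cells, in 3 samples from young and 3 from old mice, was sequenced on an Illumina platform, per the labels' protocols. The authors deposited a single table of 66712 RefSeq transcripts with an expected count and an FPKM value per transcript and sample, per the file headers. Bowtie and RSEM and the mouse build GRCm38 (mm10) are named in the submitters' processing notes, with no versions; annotation release, strand setting and read filters are not given in the sources used here. RSEM divides reads that fit several transcripts among them by a model, so an expected count need not be whole. The FPKM values deposited by the authors are scaled by transcript length and library total. Mean columns in the table differed from the means of the 3 samples by at most 3.3e-05.

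Expected counts and FPKM were summed over the transcripts of each of 19977 Entrez genes. Symbols and coordinates came from the RefSeq table of GRCm38, in which 19830 gene numbers matched and 147 did not; the unmatched ones held between 0.121% and 0.211% of a library's counts. Summed counts were rounded to whole numbers. Counting error is not small for every gene above the filter, since Myo3b, for example, had 9 counts in its lowest library. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 26.36.

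Groups and replicate numbers were read from the sample titles. The test written before the data were examined was limma on log2(FPKM + 1), unless the table held expected counts, in which case edgeR's quasi-likelihood test was to be the main one; since it did, edgeR 4.0.16 in R 4.3.3 was used, with TMM factors, no replicate block, and genes with a mean FPKM of at least 1 over the 6 samples. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error is the log2 difference divided by the square root of the quasi-likelihood F. CPM values use TMM-scaled library sizes.

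Before the data were examined, 42 gene lists were written from general knowledge, and the 37 with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Calls were also made after adjustment over the list alone. Named genes followed a rule fixed at the same time: the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, leaving out receptor segment, mitochondrial, histone and unnamed genes (6 called genes), up to 4 genes per list with the smallest p, and Cd4, Cd3e, Cd8a, Il2 and Cd69. The text gives part of the 159 genes this rule selects, and 1 gene is not reported here. Cd44, and the genes that open the last part of the closing section, were picked after their values were seen.

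On simulated data with the real means, 10509 genes and 200 changed genes, 3 against 3 in 5 runs, edgeR recovered 23.2% of changes of 1 and 87.8% of changes of 2 on the log2 scale, with 5.8% of calls false. DESeq2 1.42.0 recovered 53% and 93.4%, with 22.2% of calls false, and limma 22.2% and 87.8%, with 7.1% false. Camera found the raised set and 0 of 39 unchanged sets, drawn without correlation between genes. Apart from the changed genes, all simulated libraries were drawn alike, so none stood apart as young replicate 1 did in the real data. The rates of recovery and of false calls need not hold for the real libraries. Limma was given simulated log2 CPM there, not FPKM.

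Alternatives chosen before the data were examined were no filter, a mean FPKM of at least 5, a replicate block, leaving out each library, DESeq2, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01, quantile, TPM or TMM scaling, no variance trend, array weights, a minimum log2 change of 1, camera with an estimated correlation, and fry. Robust edgeR, RLE factors, edgeR's default filter and voom with quality weights were added after seeing the data. Figures were drawn with matplotlib 3.10.9.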

Results

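RNA was profiled from CD4+ T cells of wild-type C57BL/6 mice that were young (6 to 8 weeks) or old (11 months). The cells came from spleen and lymph nodes, were purified by flow cytometry, and were cultured for 6 hours with antibodies against CD3 and CD28, which engage the T-cell receptor complex and its main costimulatory receptor. The 6 libraries fell into 2 groups of 3, and expected counts per library totalled between 16932551 and 18708205. The sample titles give the young age as a 1-month code where the protocol gives 6 to 8 weeks, and the protocol's wording is used here. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

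The comparison asked which transcripts differ between stimulated CD4+ T cells of old and young mice. Genes called higher in the old group included 7 of 22 measured regulatory, 5 of 20 follicular helper, 7 of 35 effector and memory and 4 of 19 inhibitory-receptor genes. With an estimated correlation, camera gave these lists adjusted p of 0.0252 to 0.0385 with all libraries, but of 0.169 to 0.207 without young replicate 1, where none passed. Il21, the cytokine of follicular helper cells, stood at 67.7 ± 17.6 CPM (counts scaled by the library's TMM-adjusted total) in old against 5.48 ± 2.93 in young libraries (SD, n = 3 each). Il10, an anti-inflammatory cytokine, stood at 21.6 ± 4.93 against 2.74 ± 0.964 CPM, and Tigit, an inhibitory receptor, at 148 ± 33.0 against 30.2 ± 7.61 CPM (SD, n = 3 each). Lower in old libraries were Igf2bp3, an RNA-binding protein of fetal tissues, at 2.45 ± 0.921 against 27.4 ± 2.30 CPM, and Sox4, a transcription factor of lymphocyte progenitors, which was 8.26-fold lower than its 33.1 ± 7.80 CPM in young libraries (SD, n = 3 each). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 92 of 10509 genes passed an adjusted p of 0.05, of which 78 were higher and 14 lower in old libraries, while 1119 genes had an unadjusted p under 0.05. The groups did not overlap for any of these 92 genes, nor for 1727 genes in all (16.4%). Chance alone gives 10% on average, but with correlated genes the share in a single division of the libraries can lie far from that. It was not computed for other divisions, so an excess was not tested.

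The number of genes called rested on single libraries. Young replicate 1 stood apart, with correlations of 0.924 and 0.911 across genes with the other young libraries, which correlated at 0.977 with each other (genes are not independent replicates). Without it 929 genes passed (616 higher, 313 lower), all 92 among them. No gene passed without young replicate 2 or without old replicate 2, with 1296 and 688 genes at an unadjusted p under 0.05, and 7, 6 and 9 genes passed without young replicate 3, old replicate 1 and old replicate 3. All 92 genes kept their direction whichever library was left out. DESeq2 called 501 genes, including all 92, and limma on log2(FPKM + 1) called 99, including 78 of the 92.

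**Figure D1:**
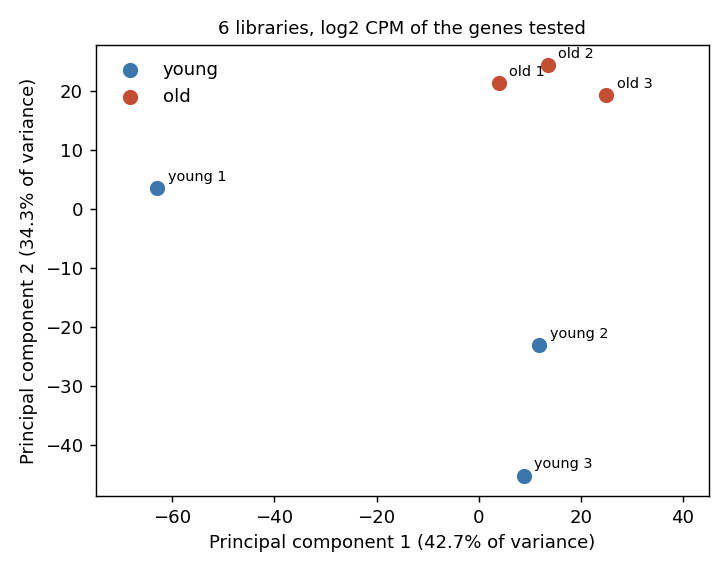
Principal components of log2 CPM for the 6 libraries, with component 1 (42.7% of variance) on the horizontal axis and component 2 (34.3%) on the vertical axis; each point is a library, coloured by age group. Young replicate 1 lies at -62.98 on component 1, where the other 5 libraries lie between 3.9 and 24.91.

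The 8 largest rises among named genes had adjusted p between 0.0142 and 0.0466 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scg2, a secretory granule protein of neuroendocrine cells (gene 20254, chromosome 1, 79434366 to 79440026 in GRCm38), rose by a log2 difference of 4.33 ± 0.38 (SE, n = 3 per group). Il21 (gene 60505, chromosome 3, 37222759 to 37232636) rose by 3.62 ± 0.45, and Spp1, the secreted phosphoprotein osteopontin, by 3.63 ± 0.55. Sostdc1, an antagonist of bone morphogenetic protein signalling, rose by 3.82 ± 0.62, and by 3.23 without old replicate 1. Ccl1, a chemokine, rose by 3.58 ± 0.53, and by 2.84 without old replicate 3. Gpm6b, a membrane glycoprotein, and Myo3b, an unconventional myosin, rose by 3.63 ± 0.47 and 3.62 ± 0.47. Lilr4b, an immunoglobulin-like receptor, rose by 3.42 ± 0.37, and since its reads can be shared with the near-identical Lilrb4a, the sum of both was also tested and rose by 3.30 ± 0.27. Limma on log2(FPKM + 1), with Benjamini-Hochberg adjustment, did not call Sostdc1 (adjusted p = 0.0835), Myo3b (0.0666) or Spp1 (0.0628).

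Among the 8 largest falls, adjusted p lay between 0.0142 and 0.0428 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Igf2bp3 (gene 140488, chromosome 6, 49085218 to 49215469 in GRCm38) had a log2 difference of -3.48 ± 0.29, and Sox4 (gene 20677, chromosome 13, 28948919 to 28953699) of -3.05 ± 0.29 (SE, n = 3 per group). Smo, the signal transducer of the Hedgehog pathway, changed by -2.23 ± 0.34. Itm2a, a membrane protein of activated T cells and thymocytes, fell from 491 ± 196 to 115 ± 27.0 CPM (SD), a log2 difference of -2.10 ± 0.33. Adcy6, an adenylyl cyclase, and Tspan9, a tetraspanin, changed by -1.89 ± 0.26 and -1.85 ± 0.25. For Amigo2, a cell adhesion molecule, and Ptprf, a receptor tyrosine phosphatase, the differences were -1.85 ± 0.27 and -1.65 ± 0.25, and limma on log2(FPKM + 1) did not call Ptprf (adjusted p = 0.0837 with Benjamini-Hochberg adjustment). Igf2bp3 overlaps Malsu1, Amigo2 overlaps Pced1b and Gpm6b overlaps Ofd1 in the gene table. Overlaps in that table are of whole gene spans, introns included, and shared transcript sequence was not checked. Where transcripts do share sequence, reads in it cannot be assigned without a stated strand.

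**Figure D2:**
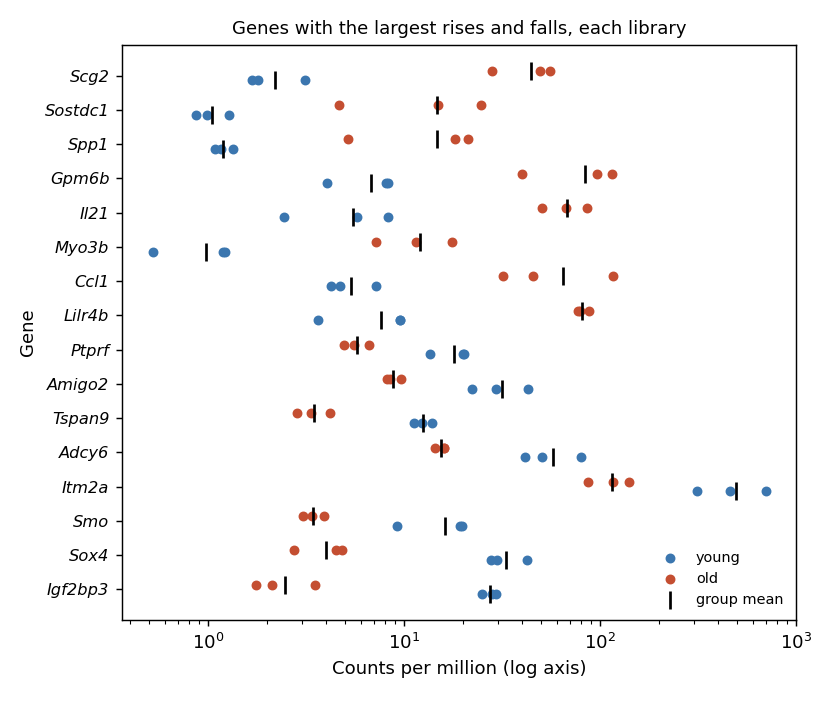
Counts scaled by the library's TMM-adjusted total (CPM, log axis) of the 8 genes with the largest rises and the 8 with the largest falls; each point is a library (n = 3 per group) and each vertical bar a group mean. Old and young libraries do not overlap for any of the 16 genes, for example Igf2bp3 with means of 2.45 and 27.4 CPM.

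The regulatory T cell list shifted upward, with a median log2 difference of 1.24 over 22 measured genes, all 22 of them positive. Of these, 7 rose over all genes tested and 18 rose when adjusted over the list alone. Ctla4, an inhibitory receptor that competes with Cd28, rose by 1.60 ± 0.20 on the log2 scale, and Ikzf2, the transcription factor Helios, by 1.77 ± 0.27 (SE, n = 3 per group). Tigit rose by 2.30 ± 0.26 (it overlaps Zbtb20 in the gene table), Il10 by 2.97 ± 0.33 and Socs2, a suppressor of cytokine signalling, by 1.29 ± 0.17. The list had an adjusted p = 1.76e-36 in camera with Benjamini-Hochberg adjustment and a preset correlation, and an adjusted p = 0.0252 with an estimated correlation. Without young replicate 1 its median was 1.22, with an adjusted p = 0.169 with an estimated correlation.

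Follicular helper genes shifted upward too, with a median of 1.28 over 20 genes, of which 5 rose over all genes tested and 14 when adjusted over the list alone. Maf, a transcription factor that drives Il21 and Il10, rose by 2.09 ± 0.25, and Tox2, a high-mobility-group factor, by 2.10 ± 0.22 (log2, SE, n = 3 per group). The camera test gave this list an adjusted p = 0.0385 with an estimated correlation, and 0.207 without young replicate 1. Inhibitory receptor and exhaustion genes had a median of 1.36 over 19 genes, with 4 higher calls over all genes tested and 13 adjusted over the list alone, and an adjusted p = 0.0252 with an estimated correlation (0.169 without young replicate 1). Tigit, Ctla4, Ikzf2 and Tox2 made up those 4 calls and also belong to the regulatory or follicular helper lists.

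Effector and memory genes had a mean log2 difference of 1.08 over 35 genes, of which 7 rose over all genes tested and 23 when adjusted over the list alone (camera, adjusted p = 0.0358 with an estimated correlation, 0.169 without young replicate 1). Cxcr6, a chemokine receptor of tissue-homing cells, rose by 3.17 ± 0.35 (it overlaps Fyco1 in the gene table), and Il1rl1, the interleukin-33 receptor, by 1.87 ± 0.22 (log2, SE, n = 3 per group). Cd44, the adhesion receptor used to mark antigen-experienced cells, was named after its value was seen, and stood at 187 CPM in old against 71.2 CPM in young libraries, a log2 difference of 1.40 ± 0.21. The Th1 list had a median of 0.85 over 15 genes, with 2 higher calls over all genes tested and 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0289 with an estimated correlation, 0.207 without young replicate 1). Nkg7, a cytotoxic granule protein, rose by 2.07 ± 0.28. The Th2 list had a median of 1.09 over 11 genes, with 2 calls (Il10 and Il1rl1) over all genes tested and 8 adjusted over the list alone (camera, adjusted p = 0.0326 with an estimated correlation, likewise 0.207 without young replicate 1).

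T-cell cytokine genes had a median of 1.88 over 25 genes, with 4 higher calls over all genes tested and 16 adjusted over the list alone, but an adjusted p = 0.113 with an estimated correlation in camera. The calls were Il21, Il10, Tnfsf8, the ligand of Cd30, and Csf1, a growth factor of macrophages. Il17a, the signature cytokine of Th17 cells, was not called and stood at 91.8 ± 120 CPM in old against 1.60 ± 0.924 in young libraries (SD, n = 3 each). Its log2 difference of 5.84 became 3.87 without old replicate 3, and that of Il5, a Th2 cytokine, also not called, went from 5.06 to 3.04. The Th17 list had a median of 1.39 over 12 genes, with 1 call (Batf) over all genes tested and 6 adjusted over the list alone, and an adjusted p = 0.133 with an estimated correlation. Chemokine genes had a median of 0.96 over 13 genes, with 2 calls over all genes tested and 6 adjusted over the list alone (adjusted p = 0.0967 with an estimated correlation). Ccl3, an inflammatory chemokine, rose by 2.82 ± 0.32, but it overlaps Ccl4, and the summed counts of both had an adjusted p of 0.0503 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The cytotoxic list had a median of 0.77 over 22 genes, with 2 higher calls (Ccl3 and Nkg7) over all genes tested and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.096 with an estimated correlation).

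Early genes of T-cell receptor stimulation had a median of 0.59 over 34 genes, 33 of them positive, with 1 call over all genes tested and 13 adjusted over the list alone (camera, adjusted p = 0.15 with an estimated correlation). Batf, an activator protein 1 factor, was that call and rose by 1.53 ± 0.18 on the log2 scale (SE, n = 3 per group). In young replicate 1, 26 of these 34 genes lay below both other young libraries. Cd69, an early activation marker, stood at 486 ± 200 CPM in old and 299 ± 84.3 in young libraries, with no call (SD, n = 3 each). Il2, the T-cell growth factor, had a log2 difference of 1.26 ± 0.53 (SE), or 0.66 without old replicate 3, and was not called either. Among genes of the sort, Cd4 had a log2 difference of 0.13 ± 0.29 and Cd3e of 0.21 ± 0.19, neither called, and Cd8a was below the expression filter at 2.09 CPM in old and 1.95 in young libraries. Cd8b1, the other CD8 chain, stood at 10.8 ± 1.69 CPM in old and 19.3 ± 5.98 in young libraries (SD, n = 3 each), with groups that do not overlap but no call (adjusted p = 0.266 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Malt1, a protease of receptor signalling, was the only call among 30 proximal signalling genes and rose by 1.19 ± 0.18, also the only 1 adjusted over the list alone (list median 0.06, camera adjusted p = 0.19). Without young replicate 1 that list had a median of 0.20 and passed camera's preset test (adjusted p = 0.0181), but had an adjusted p = 0.252 with an estimated correlation.

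Naive and quiescence genes had a median of -0.66 over 27 genes, with 0 calls in edgeR's quasi-likelihood test over all genes tested (10 at an unadjusted p under 0.05, 6 in DESeq2) and 2 lower adjusted over the list alone, and an adjusted p = 0.311 with an estimated correlation. This median moved to -0.09 and the list's preset call ended without young replicate 1 (camera adjusted p = 0.124), in which 21 of the 27 genes lay above both other young libraries. With that library left out, edgeR called 4 of the 27 genes higher and 4 lower. Ccr7, the lymph node homing receptor, stood at 574 ± 47.3 CPM in old and 1196 ± 268 in young libraries (SD, n = 3 each). Cell cycle genes had a median of -0.44 over 38 genes, 36 of them negative, with 0 calls in edgeR, over all genes or adjusted over the list alone, 5 at an unadjusted p under 0.05 and 1 in DESeq2. That list passed camera's preset test (adjusted p = 1.41e-05) and fry (adjusted p = 0.0425), but not camera with an estimated correlation (adjusted p = 0.133). Without young replicate 1 its median was -0.355 and edgeR called 7 of its genes lower (adjusted p = 0.318 in camera with an estimated correlation). Oxidative phosphorylation genes had a median of -0.24 over 57 genes. With all libraries, 0 of them were called in edgeR (over all genes or the list alone) or DESeq2, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.878 with an estimated correlation). Its preset call in camera ended without young replicate 2 (median -0.21, adjusted p = 0.253), young replicate 3 (-0.01, 0.895) or old replicate 2 (-0.15, 0.093). Without young replicate 1, in which all 57 genes lay below both other young libraries, the median was -0.42 (adjusted p = 1.01e-13 in the preset test, and adjusted p = 0.339 with an estimated correlation). Ribosome biogenesis and heat shock genes had medians of 0.03 and -0.01 with all libraries and -0.27 and -0.32 without young replicate 1, in which all 38 ribosome biogenesis genes lay below both other young libraries. Both then passed camera's preset test, but had adjusted p = 0.366 and 0.318 with an estimated correlation. Without young replicate 3 both passed it in the upward direction (medians 0.22 and 0.18, adjusted p = 0.00443 and 0.0313 in camera), and had adjusted p = 0.845 and 0.826 with an estimated correlation.

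Stress and metabolic lists held few calls. Chac1, a glutathione-degrading enzyme of the integrated stress response, rose by 1.66 ± 0.22 and was the only call of 25 unfolded protein and stress genes, with 5 adjusted over the list alone (median 0.35, adjusted p = 0.133 with an estimated correlation). Srxn1, which restores oxidised peroxiredoxins, rose by 2.99 ± 0.36 among 23 antioxidant genes, 2 of which rose when adjusted over the list alone (median -0.14, mean 0.03, camera direction down at adjusted p = 0.925). Oas1a, an interferon-induced synthetase with close paralogs that can share its reads, rose by 1.37 ± 0.19 among 38 interferon-stimulated genes, as the only 1 on either count, with a median of -0.08 (camera adjusted p = 0.734). Without old replicate 3 the interferon list had a median of -0.33 and passed the preset test (adjusted p = 2.57e-05), with an adjusted p = 0.428 with an estimated correlation. Spp1 was the only call of 20 senescence and secretory genes, with 3 adjusted over the list alone (median 0.42, adjusted p = 0.113 with an estimated correlation).

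Lists of one-carbon metabolism (median 0.21, adjusted p = 0.574 with an estimated correlation), amino acid transport (0.21, adjusted p = 0.21 with an estimated correlation) and negative regulators of receptor signalling (0.10, adjusted p = 0.113 with an estimated correlation) passed camera's preset test with 0 genes called in edgeR, where 5, 9 and 5 genes had an unadjusted p under 0.05 and DESeq2 called 3, 2 and 2. Without young replicate 1 the preset call of one-carbon metabolism ended, at a median of -0.01 (-0.005, adjusted p = 0.653), as did that of amino acid transport (median 0.29, adjusted p = 0.0609). Those that did not pass were cholesterol and lipid synthesis (median -0.17, camera adjusted p = 0.0555), cytosolic ribosomal proteins (-0.12, 0.0943), DNA repair and telomere (-0.13, 0.263), glycolysis (-0.16, 0.508), autophagy and lysosome (-0.04, 0.535), mitochondrial biogenesis (-0.05, 0.57), heat shock (0.58, with a mean of 0.07 and an upward test direction against its negative median), ribosome biogenesis (0.726) and p53 targets (-0.05, 0.788). Adjusted over the list alone, these 12 lists gave 3 higher calls for one-carbon metabolism, 1 for amino acid transport, 2 for negative regulators, 1 higher and 1 lower for glycolysis, 1 higher for p53 targets and 0 for the others.

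None of the 6 tested lists of markers of other cell types passed camera with an estimated correlation (adjusted p of 0.113 to 0.952). In fry, the NK list (adjusted p = 0.0024) and the plasma cell list (adjusted p = 0.0285) passed, and the others did not. Of the 6 measured NK genes, 3 had positive and 3 negative differences. The neutrophil list had a median of -2.03 over 8 genes, all 8 negative, with 0 calls over all genes tested in edgeR, 6 at an unadjusted p under 0.05, 4 in DESeq2 and 6 adjusted over the list alone (camera, adjusted p = 0.133 with an estimated correlation). Ngp, a neutrophil granule protein, stood at 4.58 ± 4.54 CPM in old and 21.5 ± 8.28 in young libraries, and Ltf, lactoferrin, at 0.907 ± 0.829 and 6.95 ± 2.58 CPM (SD, n = 3 each). Leaving out 1 library gave list medians from -2.94 (without old replicate 1) to -1.60 (without old replicate 2), and without old replicate 1 the log2 difference of Ngp went from -2.23 to -3.45 and that of Ltf from -2.93 to -3.89. Plasma cell, dendritic cell and NK lists had medians of 0.57, 0.50 and 0.46 with 0 calls in edgeR (2, 3 and 3 genes at an unadjusted p under 0.05, and 2, 1 and 3 in DESeq2) and adjusted p = 0.113, 0.302 and 0.113 with an estimated correlation. The preset call of the dendritic cell list ended without young replicate 1 (median 0.40, camera adjusted p = 0.0615) or old replicate 3 (0.28, 0.0687). Adjusted over the list alone, these gave 2, 1 and 3 higher calls. B cell and monocyte lists did not pass camera (adjusted p = 0.652 and 0.825), where the B cell median of 0.07 and mean of -0.13, and the monocyte mean of -0.21 and upward test direction, differed in sign, and all 14 B cell genes were higher in young replicate 1 than in both other young libraries. Lists of CD8 T cells, gamma delta and NKT cells, erythroid cells, stroma and sex-linked genes had fewer than 5 measured genes and were not tested as lists. Y-linked transcripts such as Ddx3y were present in all 6 libraries, at 117 CPM in young and 122 CPM in old.

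In all, 23 of 37 lists passed camera with a preset correlation (19 upward, 4 downward) and 6, all upward, passed with an estimated correlation. Without young replicate 1 these numbers were 26 (17 upward, 9 downward) and 0. The test with an estimated correlation has fewer residual degrees of freedom with a library left out. Other divisions of the 6 libraries into 3 and 3 shifted up to 23 lists in the preset test.

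**Figure D3:**
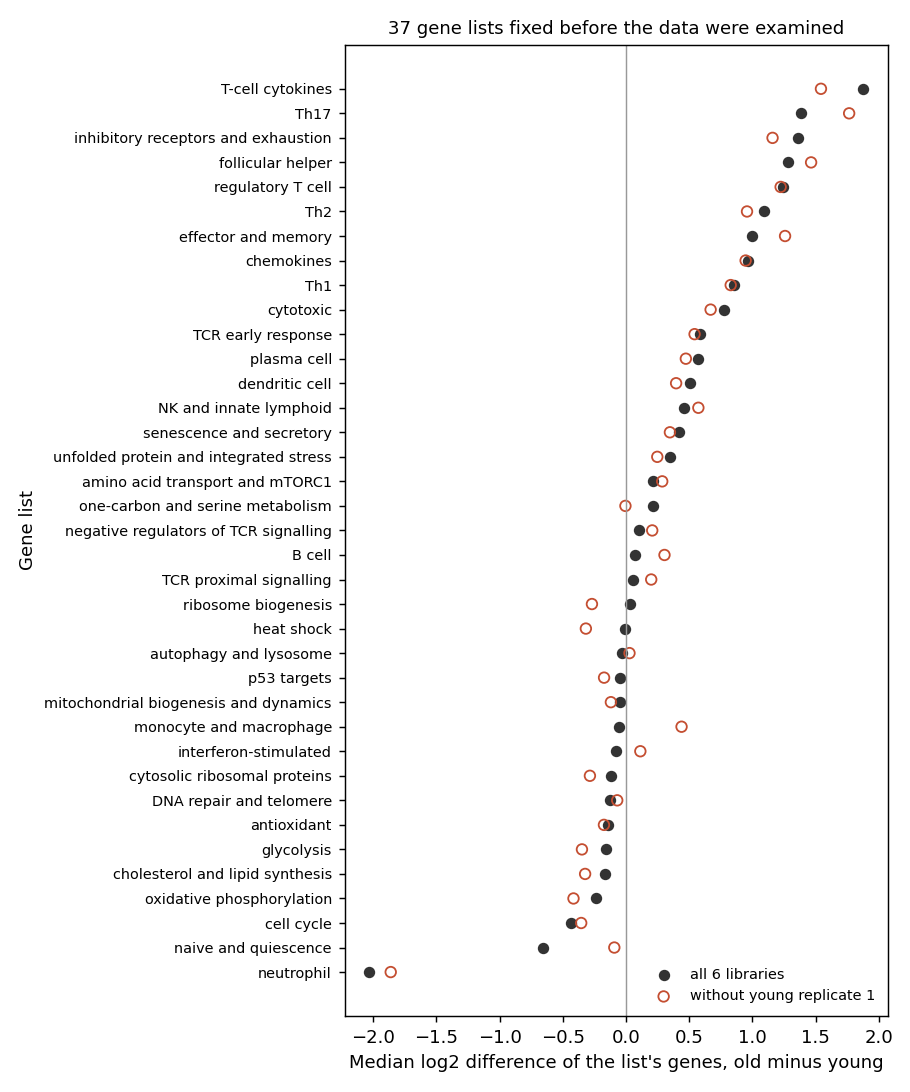
Median log2 difference, old minus young, of the measured genes of each of 37 lists (horizontal axis); filled points use all 6 libraries and open points leave out young replicate 1. The regulatory T cell list lies at 1.24 and 1.22, and the naive and quiescence list at -0.66 and -0.09.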

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

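The alternatives of robust edgeR, RLE factors, edgeR's default filter and voom weights were chosen after seeing the data. All 92 called genes kept their direction in every setting that tested them (64 were tested at a mean FPKM of at least 5). As the groups do not overlap for these genes, leaving out 1 library could hardly have turned a direction. Counts of calls (total, higher, lower) stayed within 1.5 times of 92, 78 and 14 with robust edgeR, RLE factors, edgeR's default filter, and limma on FPKM with any pseudocount, quantile or TMM scaling, or no trend. They became 203, 182 and 21 without a filter, 55, 46 and 9 at a mean FPKM of at least 5 (8042 genes tested), 501, 374 and 127 with DESeq2, and 49, 46 and 3 with limma on TPM. With limma array weights, whose fit stopped before convergence, they became 1001, 690 and 311, and with voom quality weights, which gave young replicate 1 a weight of 0.132, 629, 481 and 148. The cause was not tested for these settings. Leaving out 1 library gave 0 to 929 calls, 0 to 616 higher and 0 to 313 lower; the spread between libraries (biological coefficient of variation) was 0.271 with all libraries, 0.175 without young replicate 1 and 0.261 to 0.3 without another. A minimum log2 change of 1 kept all 92 calls.

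Whether equal replicate numbers pair the libraries is not stated, and the values do not settle it. Deviations from the group means correlated at 0.22, -0.03 and 0.18 for equal numbers. Young replicates 1 and 3 correlated best with the old library of their own number, and young replicate 2 with old replicate 3 (0.34). Deviations within a group of 3 sum to 0, so these correlations are not independent of each other. The fit with the replicate number as a block called 119 genes, 79 of the 92 among them, and 23 lists.

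The count of shifted lists was 22 to 28 in the gene-level settings other than DESeq2, in which lists were not tested (22 to 26 when leaving out 1 library). Lists were formed anew from the genes of each setting, so the number tested need not be 37 where the filter changed. With all libraries and the main filter, 6 of 37 passed with an estimated correlation and 14 with fry. Directions turned in 60 of the combinations of a named gene or list with a setting. Ribosome biogenesis (median 0.03) and heat shock (-0.01), not called with all libraries, were called lower without young replicate 1 (adjusted p = 0.366 and 0.318 with an estimated correlation), and also with array weights (-0.157 and -0.274) and with voom weights (-0.175 and -0.258); leaving out 1 library gave -0.27 to 0.216 and -0.318 to 0.184, and both were called higher without young replicate 3 (adjusted p = 0.845 and 0.826 with an estimated correlation). Cholesterol and lipid synthesis, not called with all libraries (-0.168), was called lower without young replicate 1 (-0.324, adjusted p = 0.207 with an estimated correlation), old replicate 2 (-0.223, likewise 0.695) or old replicate 3 (-0.186, likewise 0.699). Oxidative phosphorylation, called lower in the preset test (adjusted p = 0.878 with an estimated correlation), ranged from -0.416 to -0.009 when leaving out 1 library, and its call ended without young replicate 2, young replicate 3 (where its direction turned) or old replicate 2. Calls also ended without young replicate 1 for one-carbon metabolism (median -0.005), amino acid transport (0.286), naive and quiescence (-0.093) and dendritic cell genes (0.396), the last also without old replicate 3 (0.284). The other turns concern lists and genes with no call in either setting.

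For those lists, leaving out 1 library gave medians of -0.098 to 0.304 (B cell), -0.175 to -0.059 (antioxidant), -0.147 to 0.027 (autophagy and lysosome), -0.286 to 0.049 (cytosolic ribosomal proteins, called lower without young replicate 1 or old replicate 3, adjusted p = 0.392 and 0.815 with an estimated correlation), -0.349 to 0.053 (glycolysis, called lower without young replicate 1, adjusted p = 0.27 with an estimated correlation), -0.326 to 0.113 (interferon-stimulated, called lower without old replicate 3, adjusted p = 0.428 with an estimated correlation), -0.12 to 0.051 (mitochondrial biogenesis and dynamics, called lower without young replicate 1 at adjusted p = 0.0106 in camera, and adjusted p = 0.366 with an estimated correlation), -0.299 to 0.439 (monocyte and macrophage) and -0.174 to 0.049 (p53 targets). Without a filter, the medians of turned lists were 0.012 (p53 targets), -0.092 (antioxidant), 0.121 (B cell) and -0.127 (monocyte and macrophage). At a mean FPKM of at least 5 they were -0.102 (interferon-stimulated) and 0.151 (B cell), on TPM 0.112 (monocyte and macrophage), with edgeR's default filter 0.093 (B cell) and -0.264 (monocyte and macrophage), and with fry -0.141 (antioxidant). Array weights gave 0.109 (interferon-stimulated), 0.03 (autophagy and lysosome) and 0.201 (B cell), and voom weights 0.086, -0.004 and 0.215. Some of these medians keep their sign where camera's direction turned.

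For genes, leaving out 1 library gave log2 differences of -0.092 to 0.415 (Cd4), -0.068 to 0.185 (Ddx3y), -0.072 to 0.365 (Eif2s3y), -2.292 to 0.21 (Fcgr3), -0.295 to 0.051 (Gzmm), -0.736 to 0.415 (Pecam1) and -0.186 to 0.162 (Uty). Array weights gave -0.033 (Polr1a), 0.038 (Fcgr3), 0.302 (Pecam1) and 0.124 (Uty), voom weights 0.084, 0.308 and 0.122 for Fcgr3, Pecam1 and Uty, and TPM 0.001 for Uty. Of the other combinations of a named gene or list with a setting, 3722 kept direction and call, 255 lost a call and 269 gained one.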

Other observations

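Among the tests in this part, those of depth, other cell types, response strength, the regulatory list and the correlations with old libraries in young replicate 1, the regulatory, follicular helper and memory pattern and the neutrophil pattern were chosen after the result was seen; the gene-wise test for a wrong label, the divisions of the libraries and the tests of the thymocyte and inflammasome lists had bounds written before.

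Several called genes lie outside the lists of the report and were picked after their values were seen. Casp1, the protease that matures interleukin-1 beta, stood at 35.6 ± 2.07 CPM in old and 3.63 ± 1.62 in young libraries, and Casp4, its relative in the non-canonical inflammasome, at 81.3 ± 44.8 and 8.92 ± 2.11 CPM (SD, n = 3 each). Il1r2, the decoy receptor of interleukin-1, stood at 31.5 ± 2.31 CPM in old and 9.34 ± 2.39 in young libraries. A list of 8 other measured inflammasome genes had a median log2 difference of 0.24, and limma's camera test gave it p = 0.047 with a preset correlation, an adjusted p = 0.0941 over 2 such lists, and an unadjusted p = 0.294 with an estimated correlation. Without young replicate 1 the median was 0.49, with p = 0.00753 and an adjusted p = 0.0151 in limma's camera test, and an unadjusted p = 0.194 with an estimated correlation. The first value passed the bound written before, but the preset test also shifted many lists in other divisions of the libraries, so a pass with an estimated correlation was also required, a condition added after the result was seen, and a higher inflammasome programme stays open as a hypothesis. Igf2bp3 and Sox4 were followed with 14 other measured thymocyte and fetal genes, with a median log2 difference of -0.18, and that list did not pass limma's camera test, with an adjusted p = 0.127.

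The division into old and young called 92 genes and the other 9 divisions of the 6 libraries into 3 and 3 called 0 each in edgeR's test (45 to 1301 genes at an unadjusted p under 0.05, against 1119); with 10 divisions no share under 0.05 can be had. For lists, the real division shifted 23 and the highest other division also 23, with 3 of 10 divisions reaching 23.

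Young replicate 1 stood apart from the other libraries. A lower depth does not account for it, since over 3273 genes with at least 1000 counts in every library, where counting error is small, its mean correlation with the others was 0.829, below 0.907 for the next library. A first version thinned all libraries to its total, which changed no mean correlation by more than 8.48e-05 and so tests nothing. Other cells diluting the T cells, as the whole cause, would lower the receptor complex genes as much as the early response genes, but Cd3d, Cd3e, Cd3g and Cd247 had a median 0.59 above the early response list, relative to the other young libraries. All 14 B cell genes (median log2 ratio 1) and 5 of 6 monocyte genes (median 0.82) lay above both of those in it, while plasma cell and dendritic cell lists had medians of -0.42 and -0.32, so a part from B cells or monocytes stays open. For an old library under a young label, the correlations decide nothing. The highest correlation of young replicate 1 with an old library was 0.927, where old libraries correlated with each other at 0.970 or more. Its correlations with the other young libraries were 0.924 and 0.911, where those correlated at 0.977, so it stood outside both groups. Its regulatory T cell list lay at 0.15 against the other young libraries, where old libraries lay at 1.18 or higher. This argues against an old library that responded as the other old ones did, for the genes of that list. If that list follows the strength of the response, an old library with a weaker response could also lie low, which was not tested. In young replicate 1, 58.2% of the genes called without it lay nearer the old mean, which passed the bound written before for an old library. A library that differs from both groups can also lie nearer to either of them, so that bound could not tell these apart. A weaker response to the stimulation is a candidate explanation, with 26 of 34 early response genes below both other young libraries. The shift was not confined to those genes. All 57 oxidative phosphorylation genes, all 38 ribosome biogenesis genes and 47 of 49 cytosolic ribosomal protein genes also lay below both, so the early response genes do not single out this explanation. A sample from outside these 2 groups was not tested.

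The regulatory, follicular helper and effector and memory lists had positive median differences between old and young libraries. A weaker response of young replicate 1, if there was one, does not account for this, because the regulatory list had a median of 1.22 (1.223) without it, against 1.24 with all libraries. With an estimated correlation its adjusted p in camera went from 0.0252 to 0.169, that of follicular helper genes from 0.0385 to 0.207 and that of effector and memory genes from 0.0358 to 0.169. That test has fewer residual degrees of freedom with a library left out, so these rises do not by themselves show dependence on young replicate 1. A stronger response to the stimulation in all old libraries stays open. In the 6 pairs of an old and another young library, the regulatory list exceeded the early response list by 0.73 to 1.36, but lay between -0.58 and 0.80 relative to the T-cell cytokine list. Follicular helper genes exceeded these lists by 0.26 to 1.74 and -1.13 to 1.19, and effector and memory genes by 0.47 to 1.42 and -0.67 to 0.95. How far such a response shifts each list was not measured. A higher share of differentiated cells could lie behind the pattern, but the naive and quiescence list had a median of -0.093 without young replicate 1 (camera adjusted p = 0.124). Of its 27 genes, 4 were then called higher and 4 lower in edgeR. These values decide nothing, and age itself was not tested apart from such shares. Shares of cells and levels per cell cannot be told apart in bulk RNA.

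The 8 measured neutrophil genes had negative differences between old and young libraries, although CD4+ cells had been sorted. In edgeR's test 0 of them were called (6 at an unadjusted p under 0.05, 4 called in DESeq2), and camera gave the list an adjusted p = 0.133 with an estimated correlation, and 0.339 without young replicate 1. If a few neutrophils were mixed into the libraries, their genes would move together, and with the group means removed the 8 measured genes had a median pairwise Pearson r of 0.73 across the 6 libraries. A first version of this test kept the group means, which alone make the genes correlate, and gave 0.85. Their levels were low, with Ngp at 21.5 CPM and Ltf at 6.95 CPM in young libraries. Fewer neutrophils in the old libraries may therefore explain the difference, as a hypothesis, and an effect of age on the T cells was not tested against it.

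Rps27, a ribosomal protein gene, was listed at counts of 0, 0 and 2854 in young and 0, 141 and 4676 in old libraries. It is among 3 tested genes with a count of 0 in some library and of at least 500 in another, and none of the 3 was called. The summed H2-Q family had a log2 difference of 0.38 ± 0.30 (SE), while H2-Q6 alone stood at 126 CPM in old and 30.9 CPM in young libraries and was called.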
